A study of Mus musculus with 14 samples.

How the data were processed

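The series holds poly(A) RNA-seq of keratinocytes sorted from the skin of wild-type C57BL/6 mice 1 day after an intraperitoneal injection of saline or poly(I:C). The labels place the 14 samples in 4 groups: saline interfollicular epidermis (IFE; n = 4), poly(I:C) IFE (n = 3), saline bulge (n = 4) and poly(I:C) bulge (n = 3). The source field gives hair follicles for every sample, IFE samples too, so the groups follow the titles and cell type labels, and all 11 tested bulge markers were higher in the samples titled bulge. Libraries were made from total RNA with NEBNext poly(A) selection and library preparation kits, per the labels' protocols.

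The deposited table gives TPM (transcript abundance scaled for length and library total) for 28335 genes in the 14 samples. Reads were aligned with STAR and processed in Partek against the mouse build mm10, per the submitters' processing notes; versions, annotation and quantification settings are not given in the sources used here. The columns sum to between 277379 and 277719, not to the total its name implies, so the values are TPM by name and by their equal totals, on a scale 3.60 times smaller than that of a full TPM table. A pseudocount of 1 therefore weighs more than it would on a full TPM scale. Processed pseudogenes made up 35.6% to 42.8% of each library's total, so values of genes with near-identical copies, among them the MHC class I genes, are uncertain in how the reads were divided. TPM keep no depth, so the depth of the samples is unknown and no interval for counting error is given. A value of 0 in every sample was found for 67 genes.

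Values were analysed as log2(TPM + 1), and genes entered the tests if TPM was at least 1 in at least 3 of the 14 samples, which left 9848 genes, 7250 of them protein coding and 1692 processed pseudogenes. A linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend; 10 residual and 2.58 prior degrees of freedom). The 5 comparisons were poly(I:C) against saline in IFE, poly(I:C) against saline in bulge, the difference of those responses (bulge minus IFE), bulge against IFE in saline, and bulge against IFE in poly(I:C). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. These tests, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. No paired design was used, since the labels do not tie samples of different groups to the same animal.

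The 29 gene lists were fixed in advance, with 386 members named, 368 in the table and 224 tested. Of them 20 lists had at least 3 tested members and were tested with limma's fry, which asks whether the members move, on balance, one way, adjusted over the lists of a comparison. The adjusted p given with an estimated correlation is from limma's camera. Camera asks another question, whether the members move more than the other genes, so its p is not a correction of that of fry. The tested lists were antiviral interferon-stimulated genes, nucleic acid sensors and adaptors, interferon receptors and signalling, MHC class I and antigen processing, interferon-inducible GTPases, chemokines, NF-kB and inflammatory cytokine genes, immune privilege and checkpoint genes, antimicrobial and stress keratinocyte genes, cell death, proliferation, sterol synthesis, Wnt and Hedgehog pathway, basement membrane and adhesion, immediate early and heat shock, and housekeeping genes, and markers of bulge, upper hair follicle, interfollicular and sebaceous cells. The other 9 lists (interferon ligands, MHC class II, and markers of Langerhans cells, T cells, macrophages and monocytes, melanocytes, fibroblasts, endothelial cells and erythroid cells) are given as summed TPM. An interferon-stimulated gene score per sample, the mean log2(TPM + 1) of the 35 antiviral list members in the table, was compared by an exact permutation test of the difference of means, two-sided.

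Genes named in the text are the 10 genes per direction with the largest change in each response (called, groups not overlapping, mean TPM of at least 5 in a group) or with the smallest adjusted p in the other comparisons, up to 4 members per list with the smallest p, and a preset of 19 interferon and keratinocyte genes; predicted gene models and small RNA genes among them, and some other genes of this rule, are not discussed. Where a gene outside that rule is named, the text says so.

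Coordinates are those of the GENCODE M21 annotation on GRCm38, the assembly that mm10 names; 27460 of the symbols are in it and 27405 have coordinates. The GC content of a gene is that of its longest annotated transcript.

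The scripts were tested on simulated data: 200 genes were changed by known factors on each gene's mean over the 14 samples and its spread. Genes near the floor of 1 TPM were not changed, so their recovery is unknown. In the IFE response 92% of the 2-fold and 100% of the 4-fold changes were called, in the bulge response 98% and 98%, in the difference 83% and 96%, in bulge against IFE in saline 92% and 100%, and in poly(I:C) 95% and 100%. False calls were 6 of 198, 12 of 208, 1 of 180, 5 of 197 and 7 of 202. The simulated errors were independent between genes and had 1 spread per gene for all 4 groups. Correlated genes and unequal spreads were not simulated, so these rates need not apply to the data. These simulated libraries also held no trend with GC content. In a further run with such a trend in the treated libraries, 224 unchanged genes were called in the IFE response, and 0 after a GC correction.

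Alternatives chosen in advance were pseudocounts of 0.1 and 5, no filter, a filter at a mean TPM of 5, median-of-ratios scaling, eBayes without a trend, array weights, a fit on the compared groups alone, the replicate number as a block, camera with an estimated correlation for the lists, and leaving out each sample in turn. Chosen after seeing the data were a GC correction (a loess curve, span 0.5, of each library's deviation from the gene mean against GC content, subtracted), the same with the block, protein-coding genes alone with each library rescaled to an equal protein-coding total, a score over members that pass the filter, and subtraction of an estimated IFE share from the poly(I:C) bulge libraries. That share was estimated from 17 genes with a mean of at least 20 TPM in saline IFE and at most 10% of that in saline bulge, as its median and 90th percentile over these genes. Bulge-enriched genes were picked by the same rule with the populations exchanged. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.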

Results

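The series asked which keratinocytes of the skin respond to interferons. Its RNA-seq measured keratinocytes sorted from mouse skin 1 day after an injection of saline or poly(I:C), a synthetic double-stranded RNA that cells sense as viral and that induces interferons. The interfollicular epidermis (IFE) is the epidermis between the hair follicles, and the bulge is the part of the follicle that holds its stem cells. Each population had 4 saline and 3 poly(I:C) samples, and their sequencing depth is unknown because the table holds TPM. Replicates of a group were alike across all tested genes, with Pearson correlations of log2(TPM + 1) between 0.988 and 0.994. Antiviral genes varied more after poly(I:C). Their score had SDs of 0.32 in poly(I:C) IFE and 0.23 in poly(I:C) bulge, against 0.01 and 0.02 in saline. The model takes 1 spread per gene for all 4 groups. Its p-values for such genes, also between saline groups, therefore do not follow this unequal spread. The labels do not say whether the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. Levels below are means ± SD in deposited TPM, and changes are log2 fold changes ± SE with limma's adjusted p. They are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. List counts are over tested members, such as 20 of the 35 antiviral genes in the table. A gene could pass the filter on the 3 samples of a poly(I:C) group alone. Members low in saline could therefore enter only where poly(I:C) raised them, which favours rises among tested members. For lists, the adjusted p with an estimated correlation is from camera. Camera compares the members with the other genes, which is another question than that of fry.

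Poly(I:C) raised antiviral genes in IFE and in bulge, and their score rose in both. The interferon-stimulated gene score, a mean over 35 genes, was 0.75 ± 0.01 in saline IFE and 1.69 ± 0.32 in poly(I:C) IFE (n = 4 and n = 3). The difference was 0.94, with p = 0.0286 by a two-sided exact permutation test. In bulge it was 0.60 ± 0.02 in saline and 1.40 ± 0.23 after poly(I:C). The difference was 0.80, with the same p = 0.0286 by the exact permutation test, which is the smallest that 4 against 3 samples can give. The responses of the score differed by -0.14 (bulge minus IFE, p = 0.793 over 1225 splits in a two-sided exact permutation test). That test shuffles the treatment labels within each population, so its splits contain the rises themselves. It cannot decide whether the responses were equal. The difference of the responses was 0.043 without poly(I:C) IFE replicate 1, the sample with the highest score at 2.05. The size of the score depends on the pseudocount, with differences of 1.86 in IFE and 1.70 in bulge at 0.1, and of 0.46 and 0.39 at 5.

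**Figure D1:**
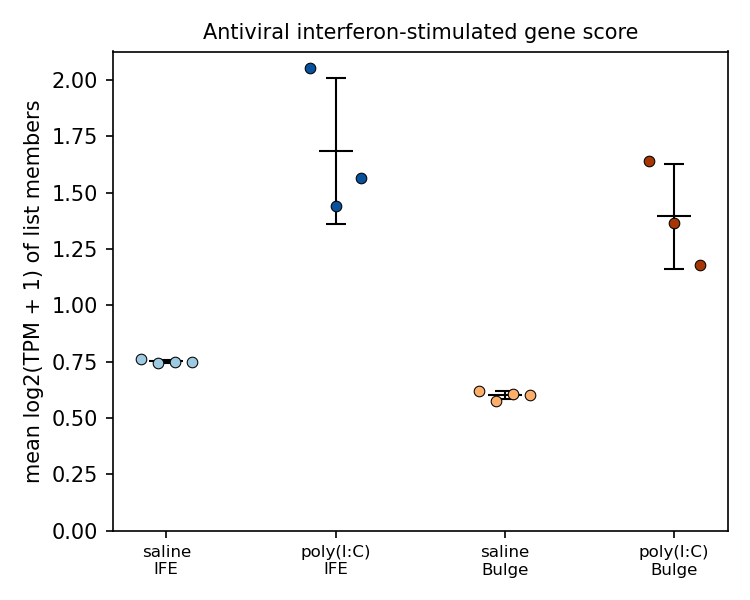
Interferon-stimulated gene score (mean log2(TPM + 1) of 35 list members) of each of the 14 samples by group, with the group mean and SD as bars. The 3 poly(I:C) IFE samples lie between 1.44 and 2.05 and the 3 poly(I:C) bulge samples between 1.18 and 1.64, all above the saline samples.

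The first comparison asked what poly(I:C) changed in IFE keratinocytes. Antiviral effectors rose: Ifi27l2a went from 2.48 ± 0.243 to 106 ± 53.6 TPM (log2 change 4.83 ± 0.27, adjusted p = 1.01e-06). Isg15, a ubiquitin-like modifier, went from 1.15 ± 0.305 to 21.5 ± 15.6 TPM (3.17 ± 0.38, adjusted p = 0.000225). Bst2, which tethers budding viruses, went from 1.83 ± 0.214 to 24.2 ± 19.0 TPM (2.90 ± 0.36, adjusted p = 0.000299). Of 20 tested antiviral genes 19 rose and 0 fell (19 and 0 adjusted over the list alone; fry adjusted p = 0.000391, adjusted p = 0.203 with an estimated correlation). Among them were the Oas family genes Oasl2 (2.50 ± 0.32) and Oas1a (1.91 ± 0.22) and the effectors Ifit1 (1.85 ± 0.27) and Ifitm3 (1.43 ± 0.16). All 5 tested interferon-inducible GTPases rose (5 over the list alone; fry adjusted p = 0.000191, adjusted p = 0.179 with an estimated correlation), with Iigp1 at 1.14 ± 0.11, Igtp at 0.99 ± 0.11 and Irgm1 at 0.94 ± 0.16. The machinery that presents antigen on MHC class I rose as well, with 16 of 19 members higher and 0 lower (16 and 0 over the list alone; fry adjusted p = 8.24e-07, adjusted p = 0.0312 with an estimated correlation). H2-T22 rose by 1.01 ± 0.09, the peptide transporter subunit Tap2 by 0.76 ± 0.07 and the immunoproteasome subunit Psmb9 by 0.75 ± 0.05. The abundant H2-K1 went from 479 ± 11.3 to 673 ± 33.7 TPM (0.49 ± 0.06, adjusted p = 0.000182).

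Interferon signalling itself also changed in IFE. Of 17 receptor and signalling genes 6 rose and 2 fell (6 and 3 over the list alone; fry adjusted p = 0.0361, adjusted p = 0.565 with an estimated correlation). Their median was -0.00 and their mean 0.46, and with median-of-ratios scaling 6 rose and 0 fell. The transcription factor Irf7 went from 1.00 ± 0.126 to 24.8 ± 23.8 TPM (3.30 ± 0.42, adjusted p = 0.000346). Irf9 rose by 1.89 ± 0.20 and the feedback inhibitor Socs1 by 0.86 ± 0.09. Of 8 nucleic acid sensors and adaptors 4 rose and 1 fell (4 and 1 over the list alone; fry adjusted p = 0.0361, adjusted p = 0.565 with an estimated correlation). The RIG-I-like receptor Dhx58 rose by 1.19 ± 0.14, the DNase Trex1 by 0.66 ± 0.09 and the RNA editor Adar by 0.64 ± 0.10, while the adaptor Mavs fell by 0.28 ± 0.06. Of the preset receptor genes, Ifnar1, for type I interferon, was 2.27 ± 0.186 and 2.07 ± 0.119 TPM (-0.09 ± 0.06, adjusted p = 0.281). Ifnlr1, for type III interferon, was 1.36 ± 0.17 and 1.03 ± 0.127 TPM (-0.21 ± 0.07, adjusted p = 0.0403). The Ifnlr1 call was lost with median-of-ratios scaling (-0.17), and with no filter. It was also lost without poly(I:C) IFE replicate 2 (-0.21) or 4 (-0.16), saline IFE replicate 2 (-0.21), 3 (-0.16) or 4 (-0.23), or saline bulge replicate 3 or 4 (-0.21 each). Ifih1, which encodes MDA5, rose by 0.34 ± 0.11 (adjusted p = 0.0369), a call lost without poly(I:C) IFE replicate 1 (0.20) or saline IFE replicate 1 (0.30), 2 (0.36), 3 (0.36) or 4 (0.35).

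Among other immune lists, 3 of 8 chemokines rose (3 over the list alone; fry adjusted p = 0.0643), led by Cxcl14 at 0.87 ± 0.17. In limma 0 of 8 NF-kB and inflammatory cytokine genes passed (0 over the list alone; fry adjusted p = 0.964), or 2 with median-of-ratios scaling and 2 after the GC correction. Cxcl10 rose by 0.47 ± 0.14 (adjusted p = 0.0271), a call lost without poly(I:C) IFE replicate 2 (0.33) or saline IFE replicate 1 (0.44), 3 (0.44) or 4 (0.43). Of 8 immune privilege and checkpoint genes 2 rose and 2 fell (2 and 2 over the list alone; fry adjusted p = 0.798), with Lgals9, a galectin ligand of T cell receptors, at 1.25 ± 0.13. All 5 tested antimicrobial and stress keratinocyte genes, of 15 in the table, rose (5 over the list alone; fry adjusted p = 0.000452, adjusted p = 0.146 with an estimated correlation), and 4 passed after the GC correction. They included Krt17 (0.69 ± 0.16), Krt6a (0.56 ± 0.13) and the defensin Defb6 (0.54 ± 0.13). B2m, the light chain of MHC class I, rose by 0.25 ± 0.07 (adjusted p = 0.0206), and this call was lost without poly(I:C) IFE replicate 1 (0.21, adjusted p = 0.08) and in a fit on the IFE samples alone (adjusted p = 0.08).

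Keratinocyte and general cell lists were tested in IFE as well. Of 11 interfollicular and differentiation markers 4 rose and 0 fell (6 and 1 over the list alone; fry adjusted p = 0.0542). Among them were the cornified envelope gene Lor (2.35 ± 0.48), Calml3 (0.70 ± 0.10) and Sbsn (0.47 ± 0.08). Proliferation genes gave 1 higher and 3 lower of 19 (1 and 7 over the list alone; fry adjusted p = 0.418). Wnt and Hedgehog pathway genes gave 3 higher of 7 (3 over the list alone; fry adjusted p = 0.0545), with Wnt4 at 0.38 ± 0.09, and 1 of the 7 after the GC correction. Basement membrane and adhesion genes gave 3 higher and 1 lower of 15 (3 and 1 over the list alone; fry adjusted p = 0.612), with the integrin gene Itga3 at 0.51 ± 0.11. Cell death genes gave 2 higher and 2 lower of 10 (2 and 2; fry adjusted p = 0.798), or 1 and 1 after the GC correction. Housekeeping genes gave 1 and 1 of 10 (1 and 1; fry adjusted p = 0.644). Immediate early and heat shock genes gave 1 higher of 13 (1 over the list alone; fry adjusted p = 0.798), the phosphatase gene Dusp1 at 1.17 ± 0.27. Upper hair follicle markers gave 1 of 5 (2 over the list alone; fry adjusted p = 0.0958), Krt79 at 0.76 ± 0.14. None of 15 sterol synthesis genes, 11 bulge markers or 4 sebaceous markers passed in limma (fry adjusted p = 0.85, 0.798 and 0.798). Krt15, Krt10, Mki67, Ly6a and Tlr3 did not pass (-0.20 ± 0.09, -0.03 ± 0.20, -0.35 ± 0.15, 0.44 ± 0.16 and -0.09 ± 0.08). Without poly(I:C) IFE replicate 2, Ly6a (0.59, adjusted p = 0.0223) and Mki67 (-0.52, adjusted p = 0.0154) passed, as did Krt15 without replicate 1 (-0.33, adjusted p = 0.0123). Krt10 was 0.030 without poly(I:C) IFE replicate 1 and with median-of-ratios scaling, and 0.018 without saline IFE replicate 3.

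In all, 1013 genes were higher and 1569 lower in poly(I:C) IFE, of which 65 and 35 changed more than 2-fold. The lower calls included Erdr1, from 8.95 ± 1.98 to 0.411 ± 0.23 TPM, and the mitochondrial ribosomal RNA mt-Rnr1, from 1711 ± 348 to 393 ± 71.2 TPM. The histone gene Hist1h2ap went from 31.4 ± 16.3 to 8.67 ± 2.46 TPM. The libraries were poly(A) selected, and whether selection or preparation changed these RNAs was not tested. Each library's deviation from the gene means had a Spearman rho with GC content of -0.31 to -0.11 in saline IFE. In poly(I:C) IFE it was 0.12 to 0.23. A separate preparation of the treated libraries cannot be told apart from poly(I:C). The transcription factor gene Cebpb rose from 6.89 ± 1.57 to 48.8 ± 13.5 TPM. The samples of both groups did not overlap for 3250 genes, 33.0% of those tested against 5.71% by chance. Median-of-ratios scaling turned the split to 1604 higher and 1436 lower, and the lower calls were 954 without poly(I:C) IFE replicate 1, 747 without replicate 4 and 984 without saline IFE replicate 4. The lower calls were 762 after the GC correction and 2903 with array weights, and a filter at a mean TPM of 5 gave 553 and 373 among 3351 genes.

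**Figure D2:**
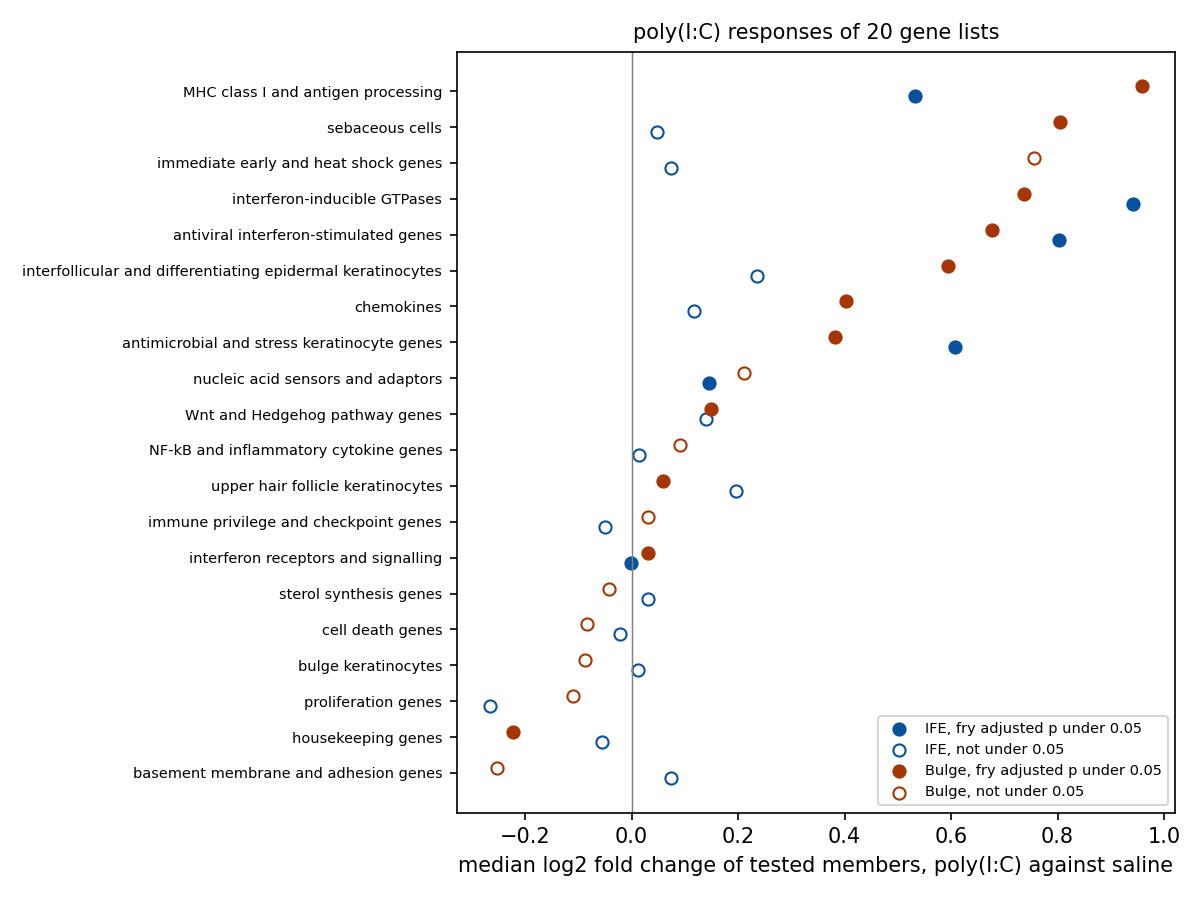
Median log2 fold change (poly(I:C) against saline) of the tested members of each of the 20 gene lists, in IFE (blue) and in bulge (brown); filled points have a fry adjusted p under 0.05. MHC class I and antigen processing has a median of 0.53 in IFE and 0.96 in bulge.

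The second comparison asked the same of bulge keratinocytes. The leading genes were the same antiviral effectors and regulators: Ifi27l2a went from 0.67 ± 0.121 to 71.8 ± 27.0 TPM (5.38 ± 0.27, adjusted p = 8.05e-08). Isg15 went from 0.369 ± 0.0459 to 17.4 ± 9.12 TPM (3.62 ± 0.38, adjusted p = 2.68e-05) and Irf7 from 0.943 ± 0.157 to 17.9 ± 7.06 TPM (3.22 ± 0.42, adjusted p = 0.000116). Of 20 antiviral genes 17 rose and 1 fell (17 and 1 over the list alone; fry adjusted p = 0.000855, adjusted p = 0.176 with an estimated correlation), and with median-of-ratios scaling 17 rose and 0 fell. Ifit1 rose by 1.81 ± 0.27, Ifitm3 by 1.80 ± 0.16 and Ifit3 by 1.48 ± 0.17. All 5 tested interferon-inducible GTPases, of 17 in the table, rose (5 over the list alone; fry adjusted p = 0.000271, adjusted p = 0.173 with an estimated correlation), with Gbp2 at 1.09 ± 0.11, Iigp1 at 0.74 ± 0.11 and Igtp at 0.68 ± 0.11. MHC class I and antigen processing gave 17 higher and 0 lower of 19 (17 and 0 over the list alone; fry adjusted p = 3.97e-09, adjusted p = 0.0124 with an estimated correlation). H2-K1 went from 111 ± 6.19 to 287 ± 16 TPM (1.36 ± 0.06, adjusted p = 1.91e-08), H2-Q4 from 8.43 ± 0.507 to 25.2 ± 1.32 TPM (1.48 ± 0.06) and H2-Q7 from 13.9 ± 0.89 to 36.6 ± 1.66 TPM (1.33 ± 0.06). B2m went from 91.2 ± 2.54 to 176 ± 2.95 TPM (0.94 ± 0.07, adjusted p = 2e-06), and Psmb9 rose by 1.17 ± 0.05.

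Of 17 receptor and signalling genes 8 rose and 2 fell in bulge (8 and 2 over the list alone; fry adjusted p = 0.016, adjusted p = 0.282 with an estimated correlation, median 0.03, mean 0.48). Irf9 rose by 1.85 ± 0.20, Irf1, a factor induced by type II interferon among others, by 0.79 ± 0.12, and Socs1 by 0.76 ± 0.09. Sensors gave 3 higher and 2 lower of 8 (3 and 2 over the list alone; fry adjusted p = 0.227), or 5 and 0 with median-of-ratios scaling, with Dhx58 at 0.67 ± 0.14. Chemokines gave 3 higher of 8 (3 over the list alone; fry adjusted p = 0.000271, adjusted p = 0.173 with an estimated correlation), or 5 with median-of-ratios scaling. Among them were the T cell attractants Cxcl10, from 0.574 ± 0.0648 to 1.89 ± 0.519 TPM, and Cxcl9, from 0.201 ± 0.0593 to 1.17 ± 0.106 TPM (0.86 ± 0.14 and 0.85 ± 0.06). Cd74, the MHC class II invariant chain, rose from 0.315 ± 0.0759 to 1.85 ± 0.237 TPM (1.11 ± 0.07, adjusted p = 9.85e-07). The NF-kB list had 1 higher of 8 (0 over the list alone; fry adjusted p = 0.409), and 4 with median-of-ratios scaling. Immune privilege genes gave 4 higher and 3 lower of 8 (4 and 3 over the list alone; fry adjusted p = 0.211), with Lgals9 at 0.65 ± 0.13. Ifnar1 fell by 0.26 ± 0.06 (adjusted p = 0.00339; -0.13 with median-of-ratios scaling), whereas Ifnlr1 (-0.12 ± 0.07), Ifih1 (0.22 ± 0.11) and Krt15 (-0.22 ± 0.09) did not pass. These became calls without some libraries: Ifnlr1 without poly(I:C) bulge replicate 1 (-0.19), Ifih1 without poly(I:C) bulge replicate 4 (0.32) or poly(I:C) IFE replicate 1 (0.22), and Krt15 without poly(I:C) IFE replicate 1 or 2 (-0.22 each). Tlr3 fell by 0.22 ± 0.08 (adjusted p = 0.0294), but was 0.076 after the GC correction. It lost its call without poly(I:C) bulge replicate 3 (-0.19) or 4 (-0.21) or saline bulge replicate 1 (-0.21) or 3 (-0.19).

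Markers of cell state moved in bulge too. Of 11 interfollicular and differentiation markers 7 rose and 1 fell (8 and 1 over the list alone; fry adjusted p = 0.000515, adjusted p = 0.173 with an estimated correlation). Ly6d (1.85 ± 0.16), Krt1 (1.66 ± 0.17) and Krt10 (1.56 ± 0.20) rose, and Calml3 fell by 0.69 ± 0.10. The upper hair follicle list gave 2 higher of 5 (2 over the list alone; fry adjusted p = 0.000515, adjusted p = 0.173 with an estimated correlation), with Krt79 from 6.29 ± 0.967 to 22.9 ± 2.23 TPM. The sebaceous list gave 3 of 4 (3 over the list alone; fry adjusted p = 0.000579, adjusted p = 0.176 with an estimated correlation), with Scd1 (1.33 ± 0.24), Elovl3 (1.22 ± 0.12) and Plin2 (0.39 ± 0.08). Bulge markers went both ways, with 2 higher and 3 lower of 11 (2 and 3 over the list alone; fry adjusted p = 0.393), or 4 and 3 with median-of-ratios scaling, where the list passed upward (fry adjusted p = 0.0234). Tbx1 rose from 29.0 ± 4.91 to 56.5 ± 1.18 TPM and Foxc1 by 0.48 ± 0.09, whereas Postn went from 299 ± 22.2 to 95.7 ± 21.3 TPM and Cd34 from 126 ± 9.13 to 77.0 ± 7.72 TPM (-0.71 ± 0.08, or -0.45 after the GC correction). Ly6a, the interferon-responsive surface protein Sca-1, rose from 1.40 ± 0.375 to 14.1 ± 1.82 TPM (2.66 ± 0.16, adjusted p = 5.26e-07). Once an estimated share of IFE RNA was subtracted from the poly(I:C) bulge libraries at its 90th percentile, Ly6a, Ly6d and Krt1 turned to -0.68, -2.93 and -0.21, H2-Q7 was 0.22 and Lgals9 0.28. Of these Ly6d passed, downwards. Ly6a, Ly6d and Krt1 are among the 17 genes from which the share was estimated, so the loss of their rise is in part built in.

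Antimicrobial genes gave 2 higher and 1 lower of 5 in bulge (3 and 1 over the list alone; fry adjusted p = 0.000983, adjusted p = 0.176 with an estimated correlation). Defb6 went from 1.47 ± 0.378 to 7.63 ± 0.981 TPM, Sprr1a rose by 1.58 ± 0.20, and Krt6a went down from 299 ± 15.9 to 146 ± 4.16 TPM. Wnt and Hedgehog genes gave 3 higher of 7 (2 over the list alone; fry adjusted p = 0.00404, adjusted p = 0.176 with an estimated correlation), or 5 with median-of-ratios scaling. Immediate early and heat shock genes gave 5 of 13 (5 over the list alone; fry adjusted p = 0.107), or 2 after the GC correction and 9 with median-of-ratios scaling. Basement membrane genes gave 2 higher and 7 lower of 15 (2 and 8 over the list alone; fry adjusted p = 0.0621), and 3 and 3 with median-of-ratios scaling. The laminin gene Lama3 fell by 0.54 ± 0.07. Cell death genes gave 0 higher and 4 lower of 10 (0 and 4; fry adjusted p = 0.0877), with Ripk3 at -0.82 ± 0.20, and 3 and 4 with median-of-ratios scaling or 0 and 2 after the GC correction. Housekeeping genes gave 1 higher and 5 lower of 10 (1 and 5; fry adjusted p = 0.016, adjusted p = 0.827 with an estimated correlation), with Rplp0 at 0.31 ± 0.04 and Ppia at -0.52 ± 0.08. Housekeeping calls were 2 and 3 with median-of-ratios scaling and 1 and 2 after the GC correction, and the list call was lost, at adjusted p = 0.359 with median-of-ratios scaling and 0.899 after the GC correction. Proliferation genes gave 1 lower of 19 (0 over the list alone; fry adjusted p = 0.682), or 2 higher and 0 lower with median-of-ratios scaling, with Mki67 at -0.11 ± 0.15. Sterol synthesis genes gave 1 higher and 1 lower of 15 (1 and 1; fry adjusted p = 0.925), or 2 and 0 with median-of-ratios scaling and 3 and 0 after the GC correction.

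In bulge 1193 genes were higher and 3696 lower, 100 and 52 of them by more than 2-fold. Cebpb rose by 3.03 ± 0.21, while Erdr1 fell by 2.56 ± 0.25 and the circadian gene Dbp by 1.96 ± 0.34. The median of all genes shifted by -0.12, so small decreases are relative to that shift, and median-of-ratios scaling gave 2345 higher and 2127 lower. The lower calls were 1829 after the GC correction and 2282 among protein-coding genes alone, rescaled to their own total. A filter at a mean TPM of 5 gave 638 and 1024 among 3351 genes, and no filter 1832 and 5726 among 28268. The samples did not overlap for 5126 genes, 52.1% against 5.71% by chance.

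**Figure D3:**
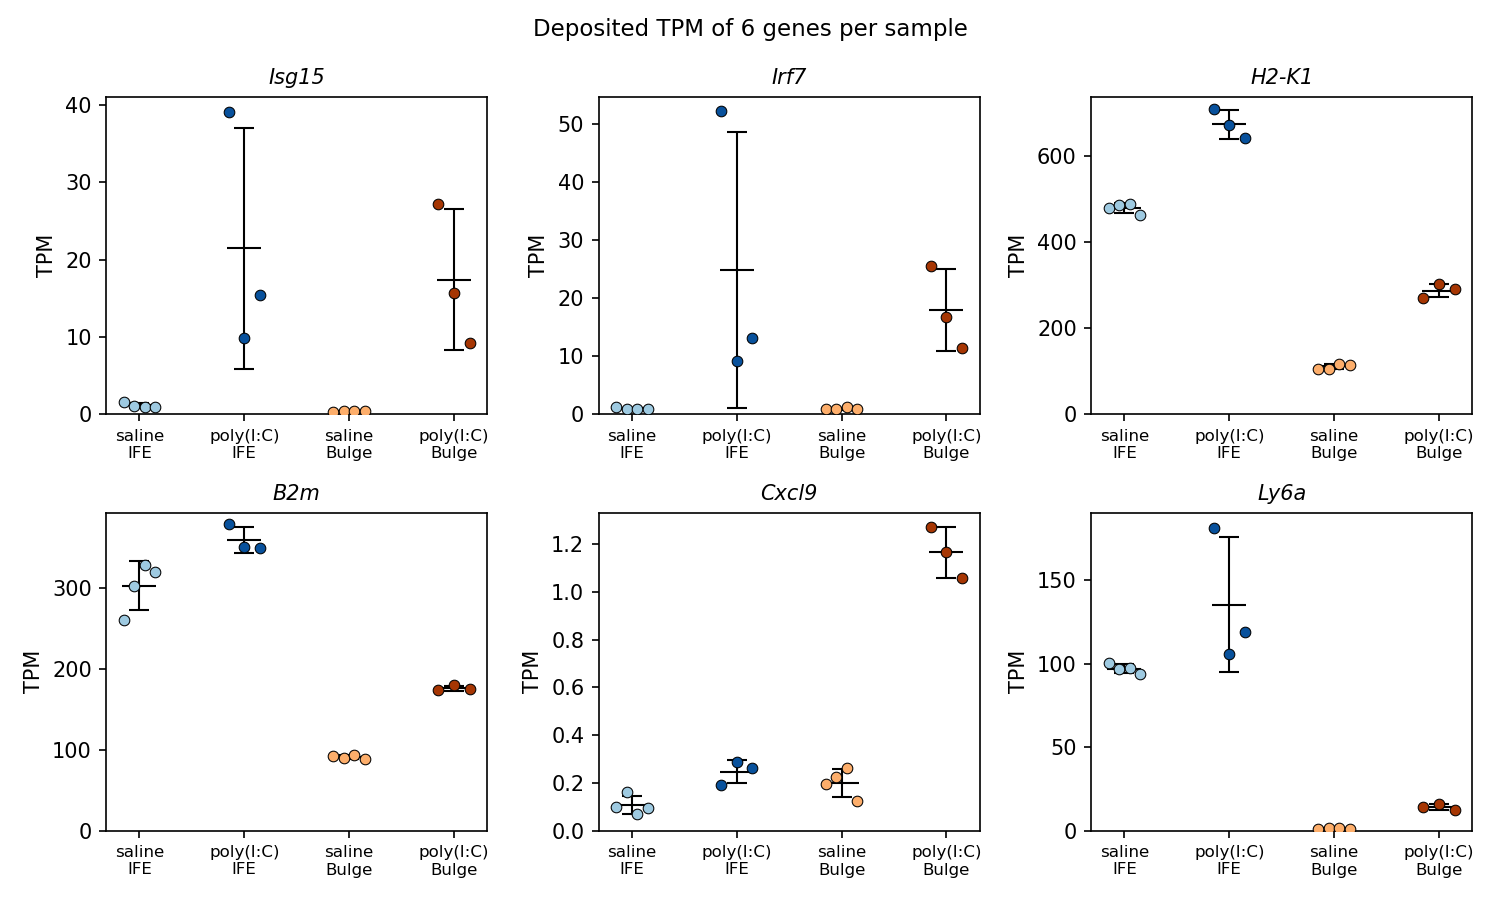
Deposited TPM of Isg15, Irf7, H2-K1, B2m, Cxcl9 and Ly6a in each of the 14 samples, with group means and SD. Cxcl9 is highest in poly(I:C) bulge at 1.17 ± 0.106 TPM, whereas H2-K1 is highest in poly(I:C) IFE at 673 ± 33.7 TPM.

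The third comparison tested whether the responses differed between the populations. Across the 9848 genes the log2 changes correlated with a Pearson r of 0.651 and a Spearman rho of 0.596 (genes are not independent replicates, and the responses share no control sample). Called in both populations were 544 higher genes, against 122.7 for independent lists, and 1256 lower genes, against 588.9. Both responses followed the GC content of the genes (Spearman rho of 0.54 in IFE and 0.48 in bulge), a shared trend that these values do not remove. The difference was called for 772 genes, 230 with a higher and 542 with a lower response in bulge. Of the 230, 129 rose in bulge without a call in IFE, 50 fell in IFE without a call in bulge, 32 rose in both and 15 fell in IFE but rose in bulge. Of the 542, 409 fell in bulge without a call in IFE and 72 rose in IFE without a call in bulge. A further 29 rose in IFE but fell in bulge, and 28 fell in both. Median-of-ratios scaling gave 378 higher and 277 lower, array weights 554 and 1019, the GC correction 397 and 450, and protein-coding genes alone, rescaled to their own total, 294 and 278. A filter at a mean TPM of 5 gave 127 and 224 among 3351 genes, and no filter gave 386 higher among 28268. The replicate number as a fixed block within treatments gave fewer calls in both directions, with the counts given under the processing below. The labels do not say whether these numbers stand for animals. The higher calls were 143 without poly(I:C) bulge replicate 1. The lower calls were 359 and 325 without poly(I:C) bulge replicate 1 or 3, 299 without poly(I:C) IFE replicate 2, 343, 334 and 361 without saline bulge replicate 1, 3 or 4, and 345 without saline IFE replicate 4.

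**Figure D4:**
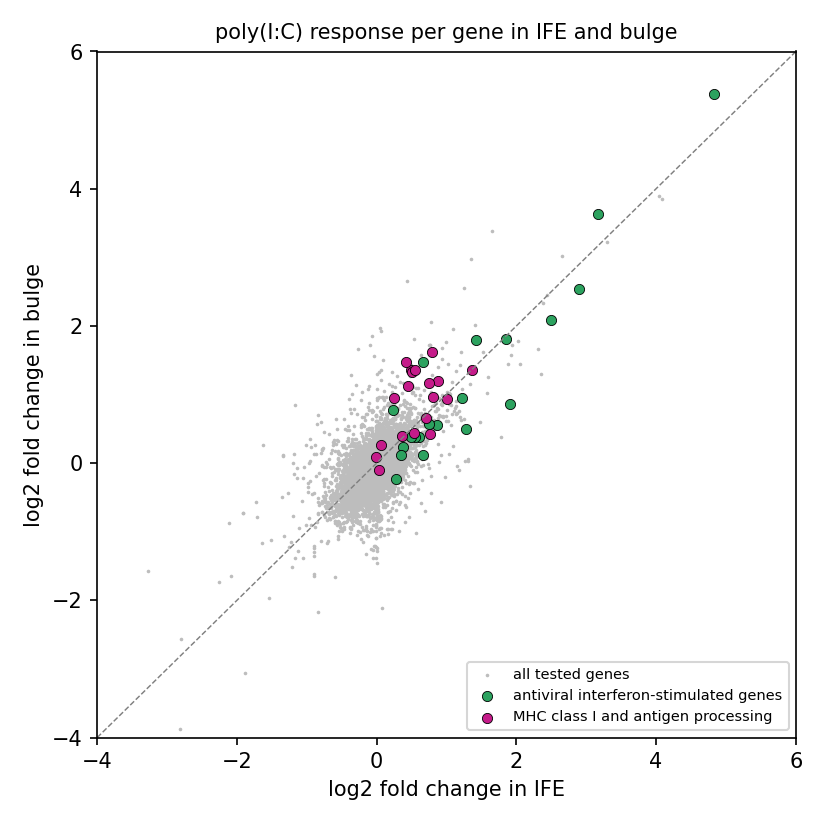
Log2 fold change (poly(I:C) against saline) of each of the 9848 tested genes in bulge against that in IFE, with the antiviral (green) and MHC class I (magenta) lists marked and a dashed line of equal response. Ifi27l2a is the marked point at the top right, at 4.83 in IFE and 5.38 in bulge.

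The antigen presentation genes responded more in bulge on the log2 scale, while the antiviral list did not pass. Reads of MHC genes may be shared with near-identical copies, so their levels are uncertain. MHC class I gave 9 of 19 members with a larger response in bulge and 0 with a smaller one (10 and 1 over the list alone; fry adjusted p = 0.000982; adjusted p = 0.138 with an estimated correlation). H2-Q4 differed by 1.05 ± 0.08 (adjusted p = 0.000101) and H2-K1 by 0.87 ± 0.08 (adjusted p = 0.00013). H2-Q7 and Psmb8 differed by 0.83 ± 0.09 and 0.83 ± 0.11, and B2m by 0.69 ± 0.10 (adjusted p = 0.0017). The 1 that rose less was Tap2 (-0.33 ± 0.10, adjusted p = 0.0544), chosen after its value was seen, which passed without poly(I:C) bulge replicate 1 (-0.39), poly(I:C) IFE replicate 2 (-0.38) or saline bulge replicate 2 (-0.36). With the 90th percentile IFE share subtracted these were 0.73, 0.52, -0.29, 0.31 and 0.43, and the calls of H2-Q7 and Psmb8 were lost. Of 20 antiviral genes 0 were higher and 2 lower (1 and 4 over the list alone; fry adjusted p = 0.669), or 0 and 1 with median-of-ratios scaling, and Isg15 (0.45 ± 0.53) and Irf7 (-0.08 ± 0.60) did not pass. Without poly(I:C) IFE replicate 1 or poly(I:C) bulge replicate 4 the estimate for Irf7 was 0.64 or 0.19. Larger responses in bulge were also found for Irf1 at 1.17 ± 0.18 (adjusted p = 0.0022), Cxcl9 at 0.68 ± 0.08 (adjusted p = 0.00047) and Cd74 at 0.85 ± 0.11 (adjusted p = 0.000738). Irf1 was 7.35 ± 1.20 TPM in saline IFE and 5.40 ± 1.13 TPM after poly(I:C), against 1.51 ± 0.117 and 3.33 ± 0.313 TPM in bulge.

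Keratinocyte genes that mark one of the populations were among those that differed. Larger responses in bulge were found for Ly6a (2.22 ± 0.23), Mt4 (2.01 ± 0.20), Krt1 (1.92 ± 0.24), Ly6d (1.92 ± 0.23), Krt10 (1.60 ± 0.29), Defb6 (1.27 ± 0.18), Elovl3 (1.15 ± 0.17), Cebpa (0.96 ± 0.12), Krt79 (0.95 ± 0.19), Dlx3 (0.95 ± 0.12) and Tbx1 (0.86 ± 0.13). Smaller responses in bulge were found for Krt6a (-1.58 ± 0.18), Calml3 (-1.39 ± 0.14), Serpinb11 (-1.29 ± 0.14), Rgs2 (-1.25 ± 0.16), Aspn (-1.24 ± 0.10), Itm2a (-1.17 ± 0.12), Clec11a (-1.11 ± 0.13), Cd34 (-0.72 ± 0.11), Duoxa1 (-0.67 ± 0.08) and Lama3 (-0.43 ± 0.10). Many of these are nearly absent from IFE, where Cd34 was 0.171 ± 0.0864 and 0.183 ± 0.0188 TPM, so their response there is near 0 on this scale. With a pseudocount of 0.1 the calls of Cd34 (-0.82), Elovl3 (1.54), Krt79 (0.74) and Tbx1 (0.43) were lost, and with the 90th percentile share subtracted Ly6a, Ly6d, Krt1 and Krt10 were -1.11, -2.86, 0.05 and 0.96, without calls (the first 3 are among the genes behind the estimated share). Among the lists the sebaceous list also passed, with 1 of 4 higher (3 over the list alone; fry adjusted p = 0.0349; adjusted p = 0.217 with an estimated correlation), or 2 of 4 with median-of-ratios scaling or after the GC correction. Interfollicular markers gave 5 higher and 1 lower of 11 (5 and 3; fry adjusted p = 0.23), basement membrane genes 0 and 4 of 15 (0 and 7; fry adjusted p = 0.171), or 0 and 2 with median-of-ratios scaling. None of the other 16 lists passed fry, with adjusted p from 0.0847 for chemokines to 0.984 for receptors and signalling.

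The fourth comparison asked how the populations differ in saline. The 11 bulge markers were all higher in saline bulge than in saline IFE (11 over the list alone; fry adjusted p = 1.17e-13; adjusted p = 0.102 with an estimated correlation), which checks the labels. Cd34 was 126 ± 9.13 against 0.171 ± 0.0864 TPM, and Tbx1 differed by 4.83 ± 0.08, Lhx2 by 4.36 ± 0.08 and Krt15 by 0.78 ± 0.09. Col8a2 (4.58 ± 0.04, adjusted p = 4.75e-17), Cyp1b1 (3.03 ± 0.03), Calml3 (8.11 ± 0.09), Grem1 (6.09 ± 0.07), Shisa2 (6.03 ± 0.07), Krt24 (6.46 ± 0.08), Timp2 (3.48 ± 0.05) and S100a4 (7.25 ± 0.10) had the smallest adjusted p among genes higher in bulge. Genes higher in IFE included Nat8l (-3.36 ± 0.06), Bmp4 (-3.36 ± 0.07), the interleukin-1 antagonist Il1rn (-3.06 ± 0.05), Cd55 (-2.90 ± 0.07) and Il1rl2 (-2.16 ± 0.05). Interfollicular markers went both ways, with 3 higher and 5 lower of 11 (3 and 5 over the list alone). Ly6d (-4.83 ± 0.15), Krt1 (-4.41 ± 0.16) and Krt10 (-3.33 ± 0.19) were lower in bulge and Sbsn (2.97 ± 0.07) was higher. Their median was 0.03 and their mean -0.42, while fry gave an adjusted p of 0.000666 upward (adjusted p = 0.861 with an estimated correlation). Ly6a was 97.1 ± 2.65 TPM in IFE and 1.40 ± 0.375 in bulge. Cd34 and Ly6a encode surface proteins commonly used to sort these cells, and the sources used here do not give the sorting gate, so their difference can come from the sort itself.

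Several immune lists differed between the populations in saline, most of them lower in bulge. The immediate early and heat shock genes, summed, were also lower, at 993 ± 186 TPM in saline bulge and 3746 ± 597 TPM in saline IFE. The values are of sorted cells, and whether the sort changed the immune lists was not tested. None passed camera with an estimated correlation, which compares a list with the other genes. MHC class I gave 0 higher and 17 lower of 19 (0 and 17 over the list alone; fry adjusted p = 2.57e-11; adjusted p = 0.126 with an estimated correlation). H2-Q7 differed by -2.93 ± 0.06, H2-K1 by -2.10 ± 0.05, B2m by -1.72 ± 0.06 and H2-T10 by -1.71 ± 0.04. NF-kB and inflammatory genes gave 7 lower of 8 (8 over the list alone; fry adjusted p = 7.95e-08, adjusted p = 0.36 with an estimated correlation), with Il33 (-2.61 ± 0.10), Tnfaip3 (-2.39 ± 0.20), Icam1 (-2.12 ± 0.15) and Nfkbiz (-1.93 ± 0.16). Receptors and signalling gave 2 higher and 10 lower of 17 (2 and 10; fry adjusted p = 2.87e-06, adjusted p = 0.543 with an estimated correlation). The interferon gamma receptor gene Ifngr1 was 13.1 ± 1.51 TPM in IFE and 1.15 ± 0.0567 in bulge, and Ifnlr1 1.36 ± 0.17 and 0.598 ± 0.0109 TPM (-0.56 ± 0.06, adjusted p = 5.29e-06). Socs3 differed by -2.34 ± 0.22, Irf1 by -1.72 ± 0.11 and Irf5 by -1.58 ± 0.07. Ifnar1 was slightly higher in bulge (0.16 ± 0.05, adjusted p = 0.0228), a call lost with protein-coding genes alone (0.08) and without saline bulge replicate 1 (0.14) or 3 (0.15) or saline IFE replicate 1 (0.13) or 4 (0.15). Sensors gave 0 higher and 4 lower of 8 (0 and 4; fry adjusted p = 0.000292, adjusted p = 0.543 with an estimated correlation), with Trex1 at -0.78 ± 0.09 and Tlr3 at -0.32 ± 0.07. Antiviral genes gave 3 higher and 6 lower of 20 (2 and 6; fry adjusted p = 0.223), with Ifitm3 at -1.95 ± 0.15, Dtx3l at -0.70 ± 0.11 and Trim25 at 0.53 ± 0.08. The score was lower in bulge by -0.15 (p = 0.0286 by a two-sided exact permutation test, n = 4 and n = 4). GTPases gave 1 higher and 2 lower of 5 (1 and 2; fry adjusted p = 0.418). Immune privilege genes gave 2 higher and 6 lower of 8 (2 and 6; fry adjusted p = 1.04e-05, adjusted p = 0.543 with an estimated correlation), with Cd200, an inhibitory ligand, at 5.99 ± 0.397 TPM in bulge and 0.0322 ± 0.0166 in IFE. Chemokines gave 2 higher and 4 lower of 8 (3 and 4), with Cxcl12 (3.26 ± 0.10) and Cxcl14 (2.17 ± 0.15) higher and Ccl27a (-1.19 ± 0.21) lower. Their median was -0.31, their mean 0.28 and fry adjusted p = 4.75e-05 upward (adjusted p = 0.924 with an estimated correlation).

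Growth and adhesion genes differed in the same samples. Proliferation genes gave 18 lower of 19 in bulge (18 over the list alone; fry adjusted p = 3.1e-05, adjusted p = 0.543 with an estimated correlation), with Cdc20 at -2.20 ± 0.13 and Mki67 at 4.53 ± 0.613 TPM in IFE and 0.559 ± 0.214 in bulge. Wnt and Hedgehog genes gave 2 higher and 5 lower of 7 (2 and 5; fry adjusted p = 5.75e-09, adjusted p = 0.543 with an estimated correlation), with Fzd10 (-4.61 ± 0.12), Wnt6 (-1.59 ± 0.05) and Axin2 (-1.54 ± 0.05) lower and Gli1 (2.03 ± 0.09) higher. Immediate early and heat shock genes gave 2 higher and 11 lower of 13 (2 and 11; fry adjusted p = 0.000409, adjusted p = 0.605 with an estimated correlation), with Junb (-3.24 ± 0.32), Nr4a1 (-3.11 ± 0.32), Atf3 (-2.76 ± 0.30) and Ier2 (-2.72 ± 0.28). Antimicrobial and stress genes gave 3 higher and 1 lower of 5 (3 and 1; fry adjusted p = 5.75e-09, adjusted p = 0.543 with an estimated correlation). Krt6a (7.31 ± 0.12) and Krt17 (3.26 ± 0.15) were higher and Krt16 (-1.76 ± 0.16) lower. Basement membrane genes gave 4 higher and 6 lower of 15 (4 and 6; fry adjusted p = 0.00383, adjusted p = 0.801 with an estimated correlation), with Krt14 at -1.83 ± 0.13 and Itga6 at -1.70 ± 0.10. Sebaceous markers gave 3 higher of 4 (3; fry adjusted p = 3.35e-05, adjusted p = 0.543 with an estimated correlation) and cell death genes 1 higher and 4 lower of 10 (1 and 4; fry adjusted p = 0.000155, adjusted p = 0.633 with an estimated correlation). Housekeeping genes gave 2 and 5 of 10 (2 and 5; fry adjusted p = 0.000136, adjusted p = 0.646 with an estimated correlation), with Rplp0 at -0.86 ± 0.04. Sterol synthesis genes gave 4 and 3 of 15 (4 and 3; fry adjusted p = 0.967) and upper follicle markers 3 and 2 of 5 (3 and 2; fry adjusted p = 0.083). In all 3267 genes were higher and 2853 lower in bulge, 591 and 552 by more than 2-fold, and the samples did not overlap for 5726 genes, 58.1% against 2.86% by chance.

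The fifth comparison asked how the populations differed after poly(I:C). The antigen presentation gap remained in direction, with 0 higher and 18 lower of 19 MHC class I genes in bulge (0 and 18 over the list alone; fry adjusted p = 2.64e-09; adjusted p = 0.19 with an estimated correlation). H2-Q7 was 161 ± 7.12 TPM in IFE and 36.6 ± 1.66 in bulge, and H2-T10 7.34 ± 0.125 and 1.72 ± 0.00863 TPM. H2-K1 was 673 ± 33.7 and 287 ± 16 TPM (-1.23 ± 0.06). B2m differed by -1.02 ± 0.07 and Psmb9 by -1.25 ± 0.06. Antiviral genes gave 2 higher and 8 lower of 20 (2 and 7 over the list alone; fry adjusted p = 0.0492; adjusted p = 0.792 with an estimated correlation). That list call was lost with median-of-ratios scaling (0.0934) and after the GC correction (0.0801). Ifitm3 (-1.58 ± 0.18) and Oas1g (-0.93 ± 0.14) were lower in bulge, whereas Isg15 (-0.19 ± 0.40) and Irf7 (-0.12 ± 0.45) did not pass. Without poly(I:C) IFE replicate 1 or poly(I:C) bulge replicate 4 the estimates for Isg15 were 0.34 and 0.17 and those for Irf7 0.59 and 0.14. The score differed by -0.29 with p = 0.4 in a two-sided exact permutation test, in which 3 against 3 samples cannot give less than 0.1. Iigp1 (-0.64 ± 0.12), Lgals9 (-1.26 ± 0.14), Trex1 (-1.11 ± 0.10), Ifngr1 (-2.36 ± 0.13) and Il33 (-2.59 ± 0.11) were lower in bulge, while Cxcl12 (3.37 ± 0.11), Cxcl9 (0.80 ± 0.06) and Cd74 (0.78 ± 0.08) were higher.

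Population markers kept their sides after poly(I:C). All 11 bulge markers were higher in bulge (11 over the list alone; fry adjusted p = 5.38e-13; adjusted p = 0.0374 with an estimated correlation), with Cd34 at 6.04 ± 0.08 and Tbx1 at 5.69 ± 0.10. Col8a2 (4.44 ± 0.04), Cyp1b1 (2.66 ± 0.04), Shisa2 (5.75 ± 0.09), Krt24 (6.07 ± 0.09), Grem1 (5.53 ± 0.09), Calml3 (6.72 ± 0.11) and Krt6a (5.72 ± 0.14) were higher. Nat8l (-2.91 ± 0.07), Bmp4 (-2.92 ± 0.08), Il1rn (-2.58 ± 0.06), Ly6a (-3.14 ± 0.17), Krt1 (-2.49 ± 0.18), Krt10 (-1.73 ± 0.22) and Mki67 (-1.59 ± 0.16) were lower. Sensors gave 0 higher and 6 lower of 8 (0 and 7 over the list alone; fry adjusted p = 5.94e-05, adjusted p = 0.476 with an estimated correlation), receptors and signalling 0 and 12 of 17 (0 and 12; fry adjusted p = 9.7e-06, adjusted p = 0.476 with an estimated correlation). NF-kB genes gave 0 and 8 of 8 (0 and 8; fry adjusted p = 5.65e-07, adjusted p = 0.301 with an estimated correlation) and proliferation genes 1 and 14 of 19 (1 and 14; fry adjusted p = 0.000195, adjusted p = 0.476 with an estimated correlation). Other lists passed fry upward in bulge: antimicrobial genes (adjusted p = 9.32e-09), sebaceous markers (7.22e-07), chemokines (3.11e-06), interfollicular markers (5.94e-05) and upper follicle markers (0.000192). With an estimated correlation their adjusted p were from 0.301 to 0.955. Interfollicular markers gave 3 higher and 5 lower of 11. In all 2252 genes were higher and 3154 lower in bulge, 493 and 487 by more than 2-fold, and the samples did not overlap for 5916 genes, 60.1% against 10% by chance.

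On GRCm38 the genes most discussed are annotated as protein coding at chromosome 4, 156199424 to 156200818 (Isg15), chromosome 7, 141262706 to 141266481 (Irf7), chromosome 12, 103442167 to 103443680 (Ifi27l2a) and chromosome 17, 33996017 to 34000347 (H2-K1). The others lie at chromosome 2, 122147686 to 122153083 (B2m), chromosome 5, 92321347 to 92328079 (Cxcl9), chromosome 15, 74994877 to 74998031 (Ly6a) and chromosome 1, 194938819 to 194961279 (Cd34).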

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

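The tests of the IFE share, the GC correction, the scaling and the starting levels were chosen after the results were seen, while the splits of the samples were planned.

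Of 19 antigen presentation genes 9 rose more in bulge than in IFE on the log2 scale and 0 less. Over the list alone Tap2, chosen after its value was seen, rose less (-0.33, limma adjusted p = 0.00873). The list had adjusted p = 0.138 in camera with an estimated correlation. The difference of the responses (bulge minus IFE) was 1.05 for H2-Q4, 0.87 for H2-K1, 0.83 for H2-Q7, 0.83 for Psmb8, 0.69 for B2m and 0.42 for Psmb9, with a median of 0.22 over the MHC class I list. The difference of the responses had little trend with GC content across genes (Spearman rho of 0.07). For the responses themselves it was 0.54 in IFE and 0.48 in bulge. So small a trend argues against GC content as the cause. All called members (9 of 9) passed after its correction, which had little to remove and is no further support. The tables also argue against IFE cells in the bulge libraries as the whole cause. The median IFE share needed was 25.4%, and 8 of 9 members needed more than 16.3%, the highest 90th percentile share of a library. IFE cells may still account for part of it, as 8 of 9 calls held with the median share subtracted and 3 of 9 with the 90th percentile. A lower starting level in bulge with an equal rise in TPM stays open: 22.2% of the called members (2 of 9) rose by more TPM in bulge. In an exact permutation test 0 of 9 rises in TPM differed at p under 0.05, but that test cannot decide this. It shuffles the treatment labels within each population, so its splits contain the rises themselves. A stronger induction in bulge and reads shared with near-identical copies were not tested and stay open too.

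Genes that mark the populations changed in the poly(I:C) bulge libraries, though not all alike: of 17 IFE-enriched genes 11 rose and 0 fell (12 and 0 with median-of-ratios scaling), and of 38 bulge-enriched genes 6 rose and 17 fell (10 and 13), with ratios of 0.246 to 2.25. For the rise, IFE cells as part of the cause cannot be told apart from a stronger response of 1 sample. Bulge replicate 1 was highest for 88.2% of the IFE-enriched genes (15 of 17). Its estimated IFE share, a median over these genes, was 6.98% against 2.13% and 3.44% in replicates 3 and 4. It also had the highest interferon-stimulated gene score (1.64 against 1.37 and 1.18). The share implied by single genes ran from -0.597% to 27.4% in replicate 1. In replicates 3 and 4 it ran from -1.88% to 14.5% and from -1.59% to 16.9%. Such unequal values argue against 1 common IFE share as the whole cause for these genes. For the median of the bulge-enriched genes (-0.23, ratio 0.850) IFE cells and scaling cannot be told apart from other causes, as it was -0.036 with the 90th percentile share subtracted and -0.051 with median-of-ratios scaling, while members went both ways. Subtraction of an IFE share and scaling each move all the bulge-enriched genes by about the same log2 amount. These corrections could therefore not even out the unequal falls, and their outcome is no test of them. After each, 34.2% of the 38 genes (13 of 38) were called lower and 10 higher, so a shift common to these genes leaves their spread. Both gene sets were also picked from the saline means that serve as their baseline. A change of the bulge cells themselves, or of which cells were sorted if the gate used Ly6a or Cd34, was not tested and stays open.

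The other genes whose responses differed were higher in bulge for Ly6a (2.22), Mt4 (2.01), Krt1 (1.92), Ly6d (1.92), Krt10 (1.60), Defb6 (1.27), mt-Rnr1 (1.24), Irf1 (1.17), Elovl3 (1.15), Cebpa (0.96), Krt79 (0.95), Dlx3 (0.95), Tbx1 (0.86), Cd74 (0.85) and Cxcl9 (0.68), and for the sebaceous list (median 0.75). They were lower in bulge for Krt6a (-1.58), Calml3 (-1.39), Serpinb11 (-1.29), Rgs2 (-1.25), Aspn (-1.24), Itm2a (-1.17), Clec11a (-1.11), Cd34 (-0.72), Duoxa1 (-0.67) and Lama3 (-0.43). The difference was called for 772 genes, and chance was not excluded for this number, since 5 of 100 splits gave as many and the highest other split gave 3593. Such splits mix poly(I:C) and saline samples within a population, so they follow the structure of the samples by treatment.

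Each gene named in the text, and the score, was checked in the 4 saline IFE and in the 4 saline bulge samples. In 25 of these 238 checks 1 sample lay far from the others, where the rule marks about 1 in 20, or 11.9. The checks share the same samples and are not independent, so 25 against 11.9 is no test of an excess. The measure is the gap to the nearest sample as a share of the range. In saline IFE replicate 1 it was 0.873 for Gli1 (higher), 0.926 for Itga3 (lower) and 0.945 for Itga6 (lower). Replicate 2 had 0.925 for Atf3 (lower) and, all higher, 0.936 for Cxcl10, 0.840 for H2-T10, 0.850 for Igtp and 0.852 for Iigp1. Replicate 3 was higher for Ly6d (0.885) and Ripk3 (0.832). Its value of 1.00 for Ifit3 says nothing, since the other 3 samples are listed at 0 and any detected level would give it. Replicate 4 was higher for Calml3 (0.937), Defb6 (0.868) and Serpinb11 (0.831). In saline bulge replicate 1 was higher for Krt17 (0.833), Nfkbiz (0.955) and Wnt6 (0.957), and replicate 2 for Krt14 (0.895) and Oasl2 (0.850). Replicate 3 was lower for Cxcl12 (0.881) and Dusp1 (0.841) and higher for Psmb9 (0.832), and replicate 4 was higher for Ifit3 (0.866), Lor (0.895) and Oas1a (0.867). Gli1 and Serpinb11 in saline IFE, and Ifit3, Oas1a, Oasl2 and Wnt6 in saline bulge, reached at most 0.0668 TPM. So near 0 their measure says little.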

How the results depend on the processing

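The GC correction, alone and with the replicate block, the IFE share, the fit on protein-coding genes and the score over filtered members were chosen after seeing the data. The cause of a change was not tested except where stated.

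Over 32 settings, the 226 named gene results gave 6302 values, of which 6187 kept their direction and side of the threshold, 55 lost a call, 35 gained one and 25 reversed. Of 400 list tests 287 kept theirs, 52 lost a call, 16 gained one and 45 reversed. Of the 16 gains, 10 came with median-of-ratios scaling and 6 after the GC correction, so some list tests given above as not passing fry passed there. Of 384 counts and scores 322 kept theirs, 47 moved, 14 lost a call and 1 reversed.

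After the GC correction the genes called were 397 higher for the difference of the responses, 762 lower in IFE and 1829 lower in bulge, and Tlr3 was 0.13 in IFE and 0.076 in bulge and Mki67 0.070 in bulge. With the replicate block added these were 548, 762 and 1811, and 0.13, 0.081 and 0.088. Lists that changed direction after the GC correction had adjusted p of 0.596 (difference) and 0.468 (bulge) for bulge markers, 0.694 (IFE) and 0.997 (bulge) for cell death, 0.423 (IFE) for housekeeping, 0.696 (difference), 0.717 (IFE) and 0.141 (bulge) for immune privilege, 0.596 (difference) for receptors, 0.947 (difference) for GTPases, 0.667 (bulge) for proliferation, and 0.730 (saline), 0.851 (difference) and 0.468 (bulge) for sterol synthesis.

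Median-of-ratios scaling gave 1604 higher in IFE, 2345 higher and 2127 lower in bulge, and 378 higher and 277 lower for the difference. Irf7 was 0.020 in the difference and Krt10 0.030 in IFE. Lists that changed direction had adjusted p of 0.992 (difference) for antimicrobial genes, 0.161 (difference) and 0.0234 (bulge, now called higher) for bulge markers, 0.643 (IFE) and 0.848 (bulge) for cell death, 0.636 (difference), 0.643 (IFE) and 0.0912 (bulge) for immune privilege, 0.636 (difference) for receptors, 0.884 (bulge) for proliferation, and 0.996 (poly(I:C)), 0.686 (saline), 0.887 (difference) and 0.506 (bulge) for sterol synthesis.

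Camera with an estimated correlation changed the direction of lists with adjusted p of 0.928 (antimicrobial, bulge markers, immune privilege, receptors, GTPases and sterol synthesis in the difference), 0.967 (bulge markers in IFE), 0.827 (bulge markers and sterol synthesis in bulge), 0.966 and 0.959 (cell death in IFE and bulge), 0.924 (chemokines in saline), 0.738 (immune privilege in bulge), 0.861 (interfollicular markers in saline), 0.858 (proliferation in bulge), 0.955 (sterol synthesis in poly(I:C)) and 0.991 (sterol synthesis in saline).

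With the 90th percentile IFE share subtracted, H2-Q7 was -0.29 in the difference, Krt1 was -0.21 in bulge, Ly6a -1.11 in the difference and -0.68 in bulge, and Ly6d -2.86 and -2.93. Krt1, Ly6a and Ly6d are among the 17 genes behind the estimate, so their change is in part built in. Array weights gave 554 higher and 1019 lower for the difference and 2903 lower in IFE, with Irf7 at 0.051 in poly(I:C) and 0.069 in the difference and Krt10 at 0.029 in IFE.

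A filter at a mean TPM of 5 tests fewer genes, 3351, and gave 553 higher and 373 lower in IFE, 638 and 1024 in bulge, 127 and 224 for the difference, 1160 and 1047 in saline and 807 and 1103 in poly(I:C). No filter tests more, 28268, and gave 1832 and 5726 in bulge, 386 higher for the difference, 6286 and 5336 in saline and 4554 and 4898 in poly(I:C). Protein-coding genes alone, with each library rescaled to an equal protein-coding total before the filter, left 7248 genes and gave 2282 lower in bulge and 278 lower for the difference. Deviations of bulge and IFE samples with the same replicate number correlated at 0.14, -0.01, 0.10 and 0.03 in saline (replicates 1 to 4) and at 0.33 and 0.29 in poly(I:C) (replicates 1 and 4). Saline replicates 2 and 4 did not correlate best with their own number, while the other 4 did, which is a hint from the data and leaves open whether the numbers pair the populations. Across treatments the correlations were -0.10 to 0.03. As a block across treatments it gave 295 lower for the difference, and within treatments as a fixed term 109 higher and 129 lower.

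Pseudocounts of 0.1 and 5 gave score differences of 1.86 and 0.46 in IFE, 1.70 and 0.39 in bulge, -0.34 and -0.08 in saline and -0.50 and -0.15 in poly(I:C), and the score over filtered members gave 1.34, 1.22, -0.24 and -0.37.

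Leaving out 1 sample at a time gave -0.60 to 0.59 for Irf7 and -0.61 to 0.34 for Isg15 in poly(I:C), -0.55 to 0.64 for Irf7 in the difference and -0.10 to 0.030 for Krt10 in IFE. Genes called were 143 to 258 higher and 299 to 645 lower for the difference and 747 to 1856 lower in IFE. The score differences were 0.75 to 1.06 in IFE and 0.67 to 0.90 in bulge, where fewer samples cannot give p under 0.0667, and -0.26 to 0.043 for the difference. Depth is unknown, so what it limits cannot be given.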

Other observations

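The tests of the GC correction and the scaling, and the choice of the genes below the filter named here, came after the values were seen, while the splits were planned.

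Some list members below the filter passed in a fit with no filter, while the lists of GTPases and of receptors and signalling did not pass in the difference of the responses (fry adjusted p = 0.778 and 0.984). The MHC class II gene H2-Ab1 went from 0.177 ± 0.0586 to 1.02 ± 0.195 TPM in bulge (adjusted p = 2.82e-05), with a response larger than in IFE (adjusted p = 0.00879), where it was 0.184 ± 0.0575 and 0.384 ± 0.0565 TPM. The T cell attractant Ccl5 went from 0.00215 to 0.231 TPM, the monocyte attractant Ccl2 from 0.110 to 0.383 TPM and the GTPase gene Gbp4 from 0.0146 to 0.196 TPM in bulge (adjusted p = 0.000291, 9.72e-05 and 1.04e-05), each with a larger response than in IFE (adjusted p = 0.0112, 0.00816 and 0.0011). In contrast, the antiviral gene Oas3 went from 0.0215 to 0.830 TPM in IFE (adjusted p = 0.00193) and had a smaller response in bulge (adjusted p = 0.047). Nearly all these levels lie below 1 TPM, some near 0, and the depth is unknown. How few reads lie behind them cannot be given, so these calls say little of how the responses differ in size.

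Other antiviral and checkpoint genes below the filter passed in 1 or both populations. Ddx58, which encodes RIG-I, went from 0.280 to 0.771 TPM in IFE and from 0.348 to 0.718 TPM in bulge (adjusted p = 0.00673 and 0.0123), and Cd274, which encodes PD-L1, from 0.175 to 0.312 and from 0.0844 to 0.323 TPM (adjusted p = 0.0357 and 0.000756). Mx1 went from 0.00957 to 0.512 TPM in IFE (adjusted p = 0.0167) and from 0.00433 to 0.271 TPM in bulge, which did not pass (adjusted p = 0.0794). These levels lie below 1 TPM at an unknown depth too, so few reads may carry them.

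The lists with too few tested members are given as summed TPM in saline IFE, poly(I:C) IFE, saline bulge and poly(I:C) bulge, in that order and without a test. Of 9 interferon ligands 1, Ifnk, was analysed here, with 0.0453, 0.0357, 0.0138 and 0.00432 TPM. MHC class II genes had 2.92, 4.25, 4.89 and 8.35 TPM. Langerhans cell markers had 0.245, 0.363, 9.75 and 7.25 TPM, of which Mfge8 alone gave 9.66 and 7.10 TPM in bulge. T cell markers had 0.129, 0.219, 0.0761 and 0.226 TPM, and macrophage and monocyte markers 0.353, 0.470, 1.17 and 0.845 TPM, with Cd68 alone at 1.16 and 0.777 TPM in bulge. Melanocyte markers had 0.120, 0.0940, 0.15 and 0.180 TPM, and fibroblast markers 0.0924, 0.133, 2.52 and 5.37 TPM. The fibroblast sums in bulge had SDs of 0.505 and 3.61, and their highest member, Col1a2, was 1.75 and 1.69 TPM there. Endothelial markers had 0.00925, 0.0106, 0.283 and 0.470 TPM, and erythroid markers 1.36, 2.48, 7.0 and 5.10 TPM, of which Hba-a2 alone gave 6.44 and 4.42 TPM in bulge. The erythroid sums in bulge had SDs of 1.48 and 2.56.

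Log2 changes after poly(I:C) followed the GC content of the genes across genes, with a Spearman rho of 0.54 in IFE and 0.48 in bulge. The tables argue against this trend as the cause of the antiviral and MHC class I rise, since 100% of the members called higher stayed so after the GC correction, 35 of 35 in IFE and 34 of 34 in bulge, with medians of 0.75 before and 0.72 after in IFE and 0.95 and 1.11 in bulge. For the lower calls in bulge the trend may be a cause: 46.0% of them (1662 of 3611) stayed after the correction. Whether scaling explains them cannot be told apart from a real decrease, as 57.5% (2127 of 3696) stayed lower after median-of-ratios scaling and the trend goes with the treatment. Each library's deviation from the gene means had a Spearman rho with GC content of -0.18 to -0.07 in saline bulge. In poly(I:C) bulge it was 0.27 to 0.33. In both populations a separate preparation of the treated libraries cannot be told apart from poly(I:C).

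Chance is unlikely, though not excluded, for the number of genes called in IFE. There 1 of 35 splits, the real one with 2582, gave as many and the highest other gave 1180. The same holds in bulge (1 of 35, with 4889 against 2845) and for bulge against IFE in saline (1 of 35, with 6120 against 1). A share of 1 of 35 is the smallest that these splits can give. In poly(I:C) the 10 splits are too few, with 5406 genes in the real split, the 1 that gave as many, and 0 in the highest other.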
